A study of Danio rerio with 4 samples.

How the data were processed

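RNA from sorted zebrafish endothelial cells of 2 genotypes was sequenced in 4 libraries, made with a SMARTer low-input kit per the labels' protocols. The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the mapped fragments of the library), with 1 column per library and 1 entry for each of 31951 Ensembl gene identifiers. Cutadapt (version not given), TopHat2 2.0.11 and Cufflinks 2.2.1 were used with genome build GRCz10, per the submitters' processing notes. The annotation, read filters, strand setting and any normalization between libraries are not given in the sources used here. FPKM values hold no counts, the low values showed no whole-read steps, and depth is therefore unknown. Cufflinks can list a gene at 0 when its estimate fails, so a gene at 0 is given library by library. Genes with near-identical copies, and overlapping or antisense genes, are uncertain because the counting rule is not known.

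Gene symbols came from a table of Ensembl identifiers and covered 26120 of the 31951 identifiers, and 16492 of the genes tested. Many of them are in capitals, in the style of human symbols, and were kept as given. No genome or annotation of this build was used here, so no coordinates are given. All 4 columns were matched to samples by name, and no column was left out.

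Each library's genotype and clutch came from its title. Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1, keeping genes with an FPKM of at least 1 in at least 2 libraries, which left 17723. A fold change on this scale understates that of low genes. The test was limma's moderated test with an intensity trend, 2 kdrl:cxcr1 against 2 wild-type libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Its degrees of freedom were 5.69, of which 3.69 came from the other genes. The median standard error of a log2 fold change was 0.623. An exact permutation of 2 against 2 libraries cannot give a two-sided p below 0.333. Every limma p-value given here therefore rests on limma's pooled spread. The clutches were separate, so the spread includes that between clutches.

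Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists that had at least 5 measured members. At the preset correlation camera compares list members with the other genes, and its certainty comes from the number of genes. Such a p-value does not measure how far a list varies from library to library. The cardiac muscle list had 2 and was not tested. Of 840 list entries, 628 matched a symbol or alias without regard to case, and cxcr2 did not. Whether cxcr2 was listed under another symbol, such as the row CXCR1, was not settled. A list's value is the median log2 fold change of its members minus that of all tested genes. Estimating the correlation per list left 0 of the 8 called lists, and fry, which asks whether a list's genes move on balance in 1 direction, called 0. With an estimated correlation camera is limited to the 2 residual degrees of freedom of the fit, so a call is hard to reach. The ribosomal list lost its call (camera p = 0.0388, adjusted p = 0.931) at an estimated correlation of -0.013, below the preset one. A call lost this way therefore does not by itself show that correlated genes made it. The ribosomal list was the exception among the called lists. The others had estimated correlations of 0.073 (proliferation) to 0.57 (mitochondrially encoded), above the preset one. For those lists, correlated genes stay a possible reason for the call.

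The lists, tests and alternatives were fixed before the data were examined, as was the rule for named genes. The rule named cxcr1 and the measured members of the CXCL8 list, then every gene past the threshold. As fewer than 20 genes passed, it went on to genes with a symbol in order of p among those whose groups do not overlap, up to 24 in all. It then named 2 to 4 members of each list by p. Some genes that the rule names, and 1 list, are not reported here. kdrl, cdh5, CXCL12, cxcl12b, the CXCR4 rows, HSP90AA1 and b2m were named after their values were seen.

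The clutch numbers pair the samples, because the labels give each clutch 1 library per genotype. Deviations from the group means correlated at 0.116 between libraries of the same clutch. A fit with the clutch as a block is given beside the count of genes, which it changed. Other alternatives were pseudocounts of 0.1 and 5, no filter, an FPKM of at least 5 in at least 2 libraries, median-of-ratios scaling, quantile normalization, no trend, robust moderation, a threshold of 0.1 and leaving out each library. A further 3 were chosen after seeing the data: matching list members to symbols in capitals without their a or b ending, the mitochondrial list without MT-CO1, and genes above 0 in all 4 libraries.

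The pipeline was tested on simulated data for this comparison, in 10 rounds over 17723 genes with 200 genes changed. Changed genes were given a simulated mean of at least 8 on the log2 scale, but kept the spread of genes near their original mean. The median log2 value of tested genes was 2.88 to 3.11 in the libraries. The shares that follow are therefore not those of real genes with so high a mean. The share of them called was 1% at 4-fold, 36.8% at 16-fold, 55% at 64-fold and 68.8% at 256-fold, with 2.2 false calls per round. A list of 60 genes shifted by 1 log2 unit had an unadjusted camera p under 0.05 in 100% of the 10 rounds, and an unshifted list in 0%. The simulated genes varied independently of each other and without a clutch effect. In the data the estimated correlation within a called list reached 0.57 (mitochondrially encoded). The rounds therefore do not show how often camera calls a list of correlated genes falsely. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.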

Results

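Zebrafish carrying kdrl:cxcr1, in which the endothelial kdrl promoter drives the CXCL8 receptor gene cxcr1, were compared with fish lacking that transgene, called wild-type here. Both lines carried kdrl:mcherry, whose red fluorescence allowed endothelial cells to be sorted from dissociated fish. RNA-seq was made from 2 independent clutches, each giving 1 library per genotype, so 4 libraries in all and 2 per group. The measurements were FPKM values for 31951 Ensembl genes. The FPKM values of a library summed to 1090468 and 1185953 in kdrl:cxcr1 clutches 1 and 2, and to 986557 and 1280969 in wild-type clutches 1 and 2. Read depth is unknown from FPKM values, so no counting error is given. A gene was listed at 0 in 31.9% of entries in both clutch 1 libraries, and in 43.5% (kdrl:cxcr1) and 42% (wild-type) of entries in clutch 2. The signal recognition particle RNA rn7sl1 made up 37.5% and 30.1% of the FPKM sum in kdrl:cxcr1 clutches 1 and 2, and 39.8% and 24% in wild-type.

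The first question was whether the receptor transcript separated the genotypes. The row cxcr1 (ENSDARG00000052088) had 12.8 FPKM in kdrl:cxcr1 clutch 1 and 8.14 FPKM in wild-type clutch 1, and was listed at 0 in both clutch 2 libraries. Its log2 fold change was 0.30 (SE 1.59; limma adjusted p = 0.981), so cxcr1 did not separate the libraries labelled kdrl:cxcr1 from those labelled wild-type. The sign turned to -1.3 without wild-type clutch 2 and to -1.6 without kdrl:cxcr1 clutch 1, and the value was 1.89 without wild-type clutch 1 and 2.19 without kdrl:cxcr1 clutch 2. A separate row under the symbol CXCR1 (ENSDARG00000054975) read 0 and 8.21 FPKM in the libraries labelled kdrl:cxcr1, and 3.89 and 0 in those labelled wild-type (log2 fold change 0.46, SE 1.33, adjusted p = 0.959; -0.69 without wild-type clutch 2 and -1.14 without kdrl:cxcr1 clutch 2). A 0 in this table cannot be taken as absence of RNA, because Cufflinks can list a gene at 0 when its estimate fails. b2m, a gene of nearly all nucleated cells chosen here after its values were seen, was also listed at 0 in kdrl:cxcr1 clutch 2. It read 5.57 to 12.7 FPKM elsewhere. The related gene b2ml read 47.1 FPKM in kdrl:cxcr1 clutch 2, so b2m alone does not settle what a 0 means. Every direction below is between libraries as labelled.

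The chemokine ligands of the receptor were measured in the same libraries. cxcl8a was 9.42 and 19.7 FPKM in kdrl:cxcr1 and 3 and 7.69 FPKM in wild-type, a log2 fold change of 1.32 (SE 0.64) that did not pass the test (limma adjusted p = 0.699) and ranged from 0.76 to 1.87 with 1 library left out. cxcl8b.1 had a log2 fold change of 0.85 (SE 0.85, adjusted p = 0.832; 0.16 to 1.53 with 1 library left out), at -0.46 in clutch 1 and 2.15 in clutch 2. For cxcl18b, a chemokine gene of fish, it was 0.33 (SE 0.46, adjusted p = 0.887; -0.02 without wild-type clutch 2). cxcl8b.3 was listed at 0 in all 4 libraries. None of the 5 tested members of the CXCL8 receptor and ligand list passed the test over all genes or when adjusted over the list alone. The median of the list lay 0.30 log2 units above that of all genes, and camera did not call it (adjusted p = 0.508). It was -0.11 without wild-type clutch 2, 0.01 without kdrl:cxcr1 clutch 2, 1.3 without wild-type clutch 1 and 1.32 without kdrl:cxcr1 clutch 1.

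**Figure D1:**
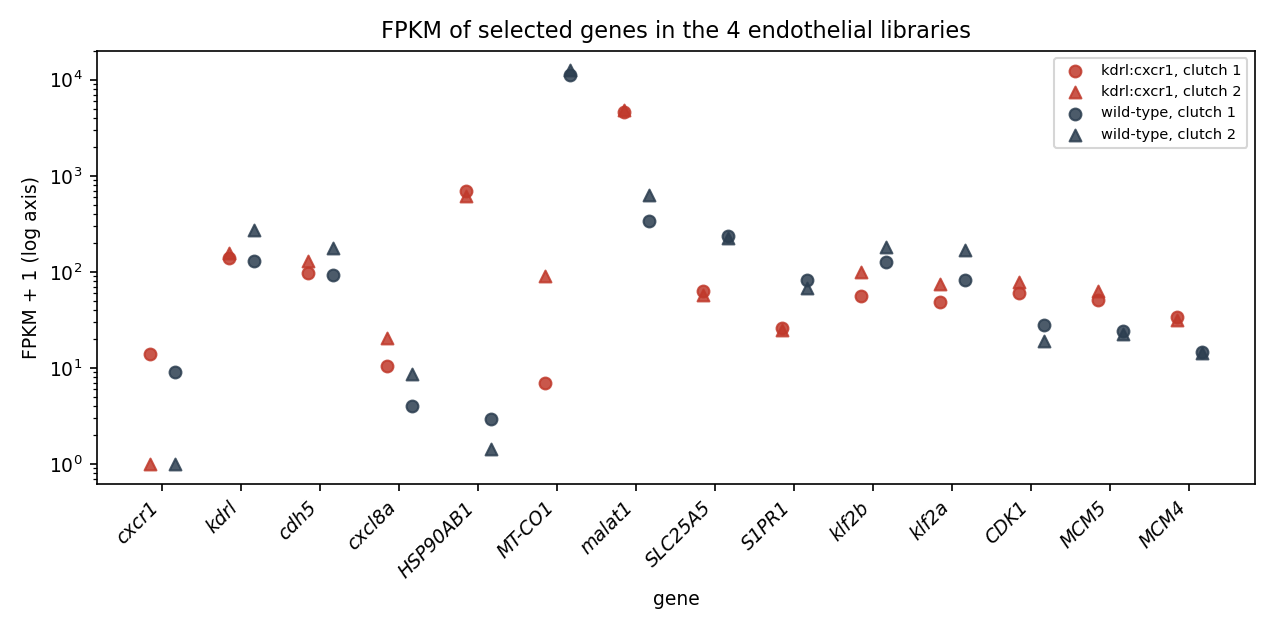
FPKM + 1 on a log axis for 14 genes in each of the 4 libraries, red for kdrl:cxcr1 and dark grey for wild-type, circles for clutch 1 and triangles for clutch 2. HSP90AB1 read 694 and 611 FPKM in kdrl:cxcr1 against 1.97 and 0.436 in wild-type, and cxcr1 was listed at 0 in both clutch 2 libraries.

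The central comparison asked which genes differed between kdrl:cxcr1 and wild-type endothelial cells. HSP90AB1, the gene of a cytosolic HSP90 chaperone, was listed higher in the libraries labelled kdrl:cxcr1. It read 694 and 611 FPKM there against 1.97 and 0.436 FPKM in wild-type (log2 fold change 8.30, SE 0.46, limma adjusted p = 0.0259). The unnamed gene ENSDARG00000080647 was listed at 0 in both kdrl:cxcr1 libraries and at 210 and 301 FPKM in wild-type, which was lower by the same test (adjusted p = 0.0259). These 2 genes, 1 higher and 1 lower, were all that passed among 17723 tested. Divisions of the 4 libraries that do not follow genotype also gave genes near 0 in 2 libraries and high in 2, as given under other observations. With the clutch as a block, 0 genes passed, with adjusted p = 0.0692 for HSP90AB1 and 0.0811 for ENSDARG00000080647. Leaving out any 1 of the 4 libraries (wild-type clutch 1, wild-type clutch 2, kdrl:cxcr1 clutch 1 or kdrl:cxcr1 clutch 2) also left 0 genes, as did a pseudocount of 0.1, no filter, or no intensity trend.

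Below the threshold, the genes with the smallest p-values were mixed in kind, and none of the genes other than HSP90AB1 and ENSDARG00000080647 passed the test. Of the 24 genes named by p-value, 12 were higher and 12 lower in kdrl:cxcr1, and 12 were listed at 0 in at least 1 library. The mitochondrially encoded cytochrome oxidase gene MT-CO1 read 5.95 and 88.6 FPKM in kdrl:cxcr1 against 11100 and 12500 FPKM in wild-type (log2 fold change -8.88, SE 1.14, adjusted p = 0.558). The nuclear non-coding RNA malat1 averaged 4710 ± 200 FPKM (SD, n = 2) in kdrl:cxcr1 and 486 ± 210 FPKM in wild-type, a log2 fold change of 3.35 with limma adjusted p = 0.653. SLC25A5, an ADP/ATP carrier of the inner mitochondrial membrane, averaged 59.3 ± 3.25 FPKM against 230 ± 4.17 FPKM, a log2 fold change of -1.94 (SE 0.30).

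Higher values in kdrl:cxcr1 were also measured for the splicing factor gene SRSF9 (log2 fold change 2.70), the fatty acid oxidation gene ECHS1 (2.41) and the ubiquitin-like modifier gene NEDD8 (2.76). The same held for the transporter gene ABCC5 (2.33), the cytokine gene IL16 (2.77), the mitochondrial genes atp5if1a (2.76) and TIMM22 (4.08, listed at 0 in wild-type clutch 2), and the minor spliceosome RNA snrnau11. snrnau11 read 132 and 523 FPKM in kdrl:cxcr1 and the chemokine receptor gene ccr12b.1 read 10.9 and 10.8 FPKM, and both were listed at 0 in wild-type. Lower values were measured for MFSD5 (log2 fold change -2.93), and for several genes listed at 0 in kdrl:cxcr1. Both kdrl:cxcr1 libraries listed 0 for 5S_rRNA (61.3 and 68.5 FPKM in wild-type), si:dkey-287f10.4 (30.8 and 57.9) and si:dkey-56e3.2 (62.1 and 19.5). TTC32, si:dkey-3e9.2 and si:dkey-253a1.2 were listed at 0 in 1 kdrl:cxcr1 library and at 1.34 FPKM or less in the other, against 15.6 to 34.4 FPKM in wild-type. At an unadjusted p under 0.05, limma gave 1206 genes, where 886 would be expected by chance if the 4 libraries were exchangeable. That expectation leaves out the pairing by clutch. Divided by clutch, the libraries gave 1630 genes, more than by genotype. With kdrl:cxcr1 clutch 1 and wild-type clutch 2 set against the other 2 they gave 474, and both divisions were chosen after seeing the data. Of the 1206 genes by genotype, 804 were higher and 402 lower. That split, 66.7% higher, was 40.9% after median-of-ratios scaling, which moved the median log2 fold change of all genes from 0.16 to -0.03. Gene lists are therefore given relative to the median of all genes.

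**Figure D2:**
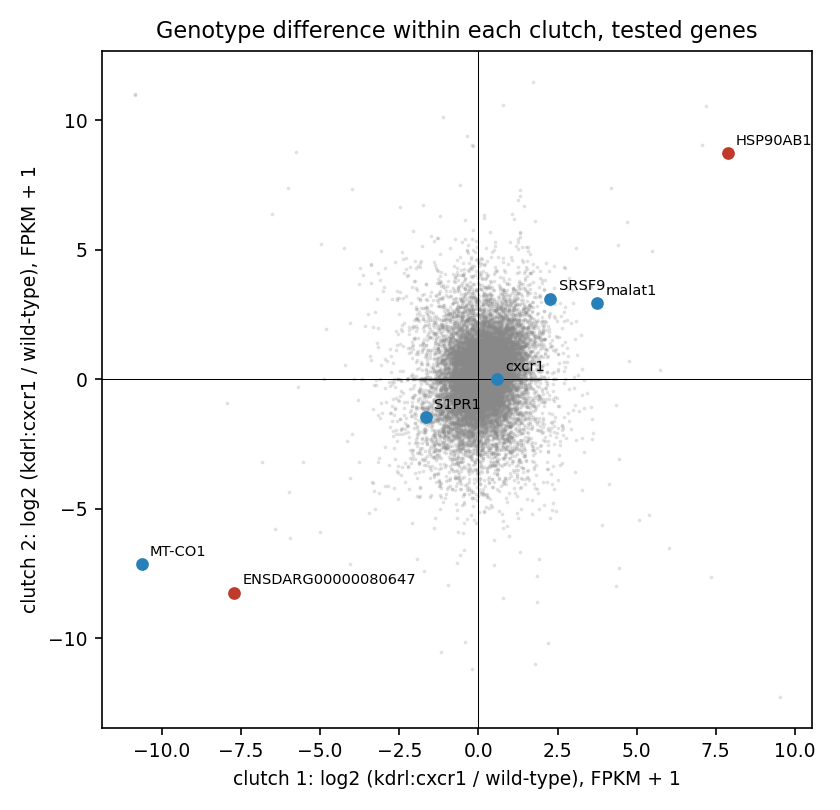
Each grey point is 1 tested gene, with the log2 ratio of kdrl:cxcr1 to wild-type (FPKM + 1) in clutch 1 on the horizontal axis and in clutch 2 on the vertical axis. The 2 red points passed the test, the labelled blue points did not, and across genes the Pearson correlation between clutches was 0.106.

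Genes of the cell cycle were higher in kdrl:cxcr1 as a group. Of 34 measured members of the proliferation list, 29 lay above the median gene, and the median of the list was 0.54 log2 units above it (camera adjusted p = 0.000251; adjusted p = 0.931 with an estimated correlation). The mitotic kinase gene CDK1 averaged 68.5 ± 12.9 FPKM (SD, n = 2) in kdrl:cxcr1 and 22.6 ± 6.56 FPKM in wild-type. The replication helicase genes MCM5 (56.2 ± 9.02 against 22.6 ± 1.36 FPKM), MCM4 (31.6 ± 1.32 against 13.5 ± 0.392) and MCM2 (40.7 ± 5.94 against 17.9 ± 5.32) were also above wild-type in both clutches. Below the median gene lay 5 members, named after their values were seen. They were CCNE1 (log2 fold change -0.89), plk1 (-0.82), CCNB1 (-0.53), CCNB2 (-0.35) and the Ki67 gene mki67 (-0.10). In this list 0 members passed over all genes and 0 adjusted over the list alone. The list median was 0.35 without kdrl:cxcr1 clutch 2, still called by camera (adjusted p = 0.017).

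Ribosomal protein transcripts were higher by a smaller amount, with 50 of 70 rows above the median gene and a median 0.24 above it (camera adjusted p = 0.00106; adjusted p = 0.931 with an estimated correlation). RPL24 averaged 186 ± 59.1 FPKM in kdrl:cxcr1 and 49.3 ± 16.2 FPKM in wild-type, RPS7 988 ± 137 and 316 ± 73.6, RPL4 1486 ± 55.2 and 539 ± 107, and RPS15 408 ± 19 and 175 ± 29.3. No member passed over all genes or adjusted over the list alone (0 and 0). The median was 0.12 without wild-type clutch 1.

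Markers of blood cells, included because a sort can carry them along, were higher in kdrl:cxcr1 beside the proliferation list. The erythroid list had 11 of 14 members above the median gene and a median of 0.61 (camera adjusted p = 0.034; adjusted p = 0.931 with an estimated correlation). Its first members were the carbonic anhydrase gene cahz (36.3 ± 0.272 against 15.2 ± 3.1 FPKM), the globin gene hbae1.1 (17.4 ± 4.27 against 5.16 ± 2.04), the spectrin gene SPTB (14.3 ± 5.52 against 5.28 ± 0.457) and the haem synthesis gene alas2 (18.3 ± 3.76 against 5.51 ± 6.34). The neutrophil and macrophage list had 19 of 23 above and a median of 0.57 (camera adjusted p = 0.0192; adjusted p = 0.931 with an estimated correlation). Its median was -0.11 in clutch 1 and 0.90 in clutch 2. Setting kdrl:cxcr1 clutch 1 and wild-type clutch 2 against the other 2 libraries, a division chosen after seeing the data, also called it, with a smaller p (median -0.56, adjusted p = 0.00427; adjusted p = 0.839 with an estimated correlation). By genotype it was led by npsn (578 ± 8.1 against 212 ± 113 FPKM), MFAP4 (38.2 ± 13.4 against 12.7 ± 5.93) and cd68 (46.2 ± 32.7 against 12.4 ± 1.97), while c1qc was listed at 0 in kdrl:cxcr1 and at 1.84 and 10.4 FPKM in wild-type. Neither list had a member that passed, over all genes (0) or adjusted over the list alone (0). The erythroid call was lost without wild-type clutch 2 (median 0.22) and without kdrl:cxcr1 clutch 1 (0.42), and the median was 0.93 without wild-type clutch 1 and 1.24 without kdrl:cxcr1 clutch 2. The neutrophil and macrophage call was lost without wild-type clutch 1 (0.55), wild-type clutch 2 (0.43) and kdrl:cxcr1 clutch 2 (-0.02), and the median was 0.99 without kdrl:cxcr1 clutch 1. Both calls were also lost without the intensity trend.

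The flow-responsive list, genes that endothelial cells regulate with blood flow, was lower in kdrl:cxcr1. All 9 measured members lay below the median gene, and the median was -1.06 (camera adjusted p = 0.00106; adjusted p = 0.931 with an estimated correlation). S1PR1, a sphingosine 1-phosphate receptor gene of endothelium, averaged 24.6 ± 0.905 FPKM in kdrl:cxcr1 and 74.7 ± 10.6 FPKM in wild-type (log2 fold change -1.56, SE 0.33). It was the 1 member that passed adjusted over the list alone (limma adjusted p = 0.0355), and 0 passed over all genes. The flow-induced transcription factor genes klf2b (76.6 ± 29.9 against 154 ± 38.4 FPKM) and klf2a (60.7 ± 18.4 against 126 ± 62) and the endothelin gene edn1 (2.24 ± 0.633 against 9.36 ± 7.17) were below wild-type in both clutches. Without wild-type clutch 2 the call was lost (median -0.48, adjusted p = 0.152).

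Mitochondrially encoded transcripts were lower, with 11 of 13 below the median gene and a median of -0.67 (camera adjusted p = 0.0132; adjusted p = 0.931 with an estimated correlation), at -0.12 in clutch 1 and -1.15 in clutch 2. MT-CO1 passed adjusted over the list alone, as the 1 such member, and 0 passed over all genes. MT-CYB averaged 3977 ± 385 FPKM against 7590 ± 3056 FPKM in wild-type, while MT-ND6 (4903 ± 11.5 against 2252 ± 1505) and MT-ND1 (1003 ± 205 against 620 ± 184) were above wild-type. The call was lost when MT-CO1 was left out of the list, a check chosen after seeing the data (median -0.60, adjusted p = 0.112). It was also lost without a filter on low values, without wild-type clutch 2 (median -0.27) and without kdrl:cxcr1 clutch 2 (-0.55).

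Markers of epidermis and of liver, gut, pancreas and yolk, which the sort was meant to exclude, were lower in kdrl:cxcr1. The epidermal list had 22 of 26 members below the median gene and a median of -0.97 (camera adjusted p = 0.000185; adjusted p = 0.931 with an estimated correlation). The keratin genes krt4 (143 ± 138 against 361 ± 25.3 FPKM) and krt5 (36.1 ± 21.3 against 82 ± 31.3) and the epithelial genes agr1 (19.1 ± 17.8 against 46.2 ± 1.32) and epcam (14.2 ± 15.4 against 37.7 ± 10.1) led it. Its median was -0.24 in clutch 1 and -1.63 in clutch 2. The call was lost without kdrl:cxcr1 clutch 2 (median -0.37, adjusted p = 0.212), and the median was -1.63 without kdrl:cxcr1 clutch 1. The liver, gut, pancreas and yolk list had 13 of 14 members below the median gene and a median of -1.39 (camera adjusted p = 0.00011; adjusted p = 0.931 with an estimated correlation). The apolipoprotein genes apoa2 (23.2 ± 24.7 against 65.7 ± 10.2 FPKM) and apoc1 (3.28 ± 2.45 against 10 ± 4.62) and the transferrin gene tfa (9.97 ± 7.95 against 24.8 ± 10.7) were below wild-type in both clutches. FABP2, a fatty acid binding protein gene of the gut, was 1.26 and 0 FPKM against 4.15 and 4.6 FPKM. In both lists 0 members passed over all genes and 0 adjusted over the list alone, and the liver list median was -0.88 without wild-type clutch 2. The stricter filter also ended the call of the liver, gut, pancreas and yolk list.

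**Figure D3:**
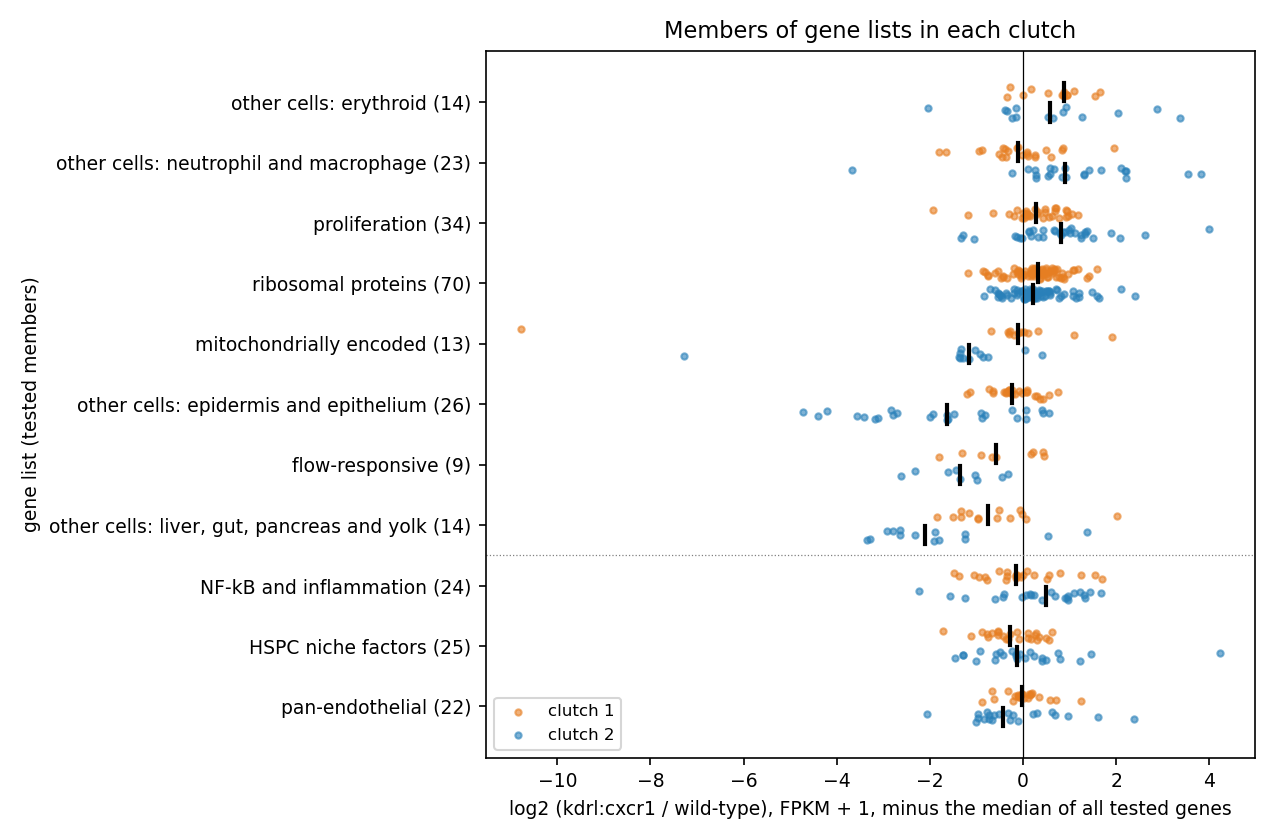
Each point is 1 member of a gene list, placed at its log2 ratio of kdrl:cxcr1 to wild-type (FPKM + 1) minus the median of all tested genes, orange for clutch 1 and blue for clutch 2, with black bars at list medians. The 8 lists above the dotted line were called by camera, with the epidermal median at -0.24 in clutch 1 and -1.63 in clutch 2, and the 3 below were not.

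Genes that mark endothelium itself were not called as a group. kdrl, the gene of a VEGF receptor, averaged 148 ± 12 FPKM in kdrl:cxcr1 and 201 ± 103 FPKM in wild-type (log2 fold change -0.34; 0.20 without wild-type clutch 2). The cadherin gene cdh5 averaged 112 ± 23.2 and 135 ± 60.3 FPKM (-0.21; 0.25 without wild-type clutch 2). Both were members of the pan-endothelial list picked after their values were seen. That list had a median of -0.21 over 22 members (camera adjusted p = 0.652), led by TAL1 (log2 fold change 1.96) and plvapb (-0.59). The arterial list had a median of -0.14 (adjusted p = 0.508), led by TBX20 (-1.37) and HEY2 (0.64). The venous and sinusoidal list stood at -0.09 (adjusted p = 0.766), led by TLL1 (-1.0, and -1.64 to -0.36 with 1 library left out) and lyve1a (-1.39, and -2.16 to -0.61, with a log2 ratio of 0.03 in clutch 1), and the tip cell and VEGF list at -0.13 (adjusted p = 0.508), led by the apelin gene APLN (0.98). Without wild-type clutch 1, camera called the pan-endothelial (-0.55) and tip cell (-0.69) lists lower.

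Factors through which a vascular niche acts on haematopoietic stem and progenitor cells, the subject of the study, likewise gave no call. The niche list had a median of -0.14 over 25 members, 9 above and 16 below the median gene (camera adjusted p = 0.508), and -0.33 to -0.09 with 1 library left out, the first without wild-type clutch 2. Its first members were the growth factor genes pdgfba (24.6 ± 6.65 FPKM in kdrl:cxcr1 against 52.8 ± 17.6 in wild-type) and tgfb1a (20.6 ± 5.56 against 37 ± 1.25), the Kit ligand gene kitlga (20.2 ± 0.195 against 34.8 ± 1.11) and GAS6 (27.4 ± 4.43 against 15.2 ± 0.933). None passed the test over all genes or adjusted over the list alone (0 and 0). The niche chemokine rows, picked after their values were seen, read 124 ± 36.8 against 171 ± 20.3 FPKM for CXCL12 and 117 ± 37.6 against 172 ± 70 FPKM for cxcl12b, and neither passed the test (limma adjusted p = 0.754 and 0.779). With 1 library left out the log2 fold change ran from -0.79 to -0.18 for CXCL12 and from -0.96 to -0.11 for cxcl12b. Of the 2 rows named CXCR4, ENSDARG00000041959 averaged 67.7 ± 2.05 against 53.8 ± 0.226 FPKM and ENSDARG00000057633 averaged 3.73 ± 3.08 against 6.27 ± 3.01 FPKM, with limma adjusted p = 0.817 and 0.836, the latter at -1.44 to -0.01 with 1 library left out. Markers of haematopoietic stem and progenitor cells had a median of 0.33 (camera adjusted p = 0.508), led by IKZF1 (log2 fold change 2.08) and TAL1.

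Signalling and inflammatory lists were not called. The Notch list had a median of 0.02 (camera adjusted p = 0.898), led by her4.2 (log2 fold change 2.1) and mfng (-0.97). The NF-kB and inflammation list stood at 0.06 (adjusted p = 0.597), led by the inhibitor gene NFKBIE (1.2) and by il6, which was listed at 2.23 and 2.58 FPKM in kdrl:cxcr1 and at 0 in both wild-type libraries. The interferon list stood at 0.09 (adjusted p = 0.764; isg20 1.34 and IRF8 1.52). The GPCR and chemokine list stood at -0.06 (adjusted p = 0.807; S1PR1 -1.56 and rac2 1.23). The adhesion and basement membrane list stood at -0.10 (adjusted p = 0.898; COL4A1 0.86 and ITGAV -1.05), and the matrix remodelling list at -0.02 (adjusted p = 0.987; plaua 1.25 and LOX -1.32). With 1 library left out, the interferon median ran from 0 to 0.28, isg20 from 1.01 to 1.67 and IRF8 from 0.78 to 2.25. The log2 fold change of her4.2 ran from 1.42 to 2.77, that of ITGAV from -1.55 to -0.56, that of plaua from 0.71 to 1.8 and that of LOX from -1.92 to -0.72.

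Stress and metabolic lists were not called either. The dissociation and stress list stood at -0.14 (camera adjusted p = 0.505), led by the heat shock gene hsp70l (611.9 ± 45.3 against 1318 ± 58 FPKM) and DUSP5 (log2 fold change -1.07), and was called lower without kdrl:cxcr1 clutch 2 (-0.52). Hypoxia and glycolysis genes stood at 0.26 (adjusted p = 0.524; LDHA 1.5 and GAPDHS 1.11), and lipid and cholesterol metabolism at -0.28 (adjusted p = 0.528; LPL -1.68 and abca1b -0.95). With 1 library left out, the hypoxia and glycolysis median ran from 0.15 to 0.59 (0.59 without wild-type clutch 1), LDHA from 1.19 to 1.82 and GAPDHS from 0.56 to 1.66. The lipid median was 0.36 without wild-type clutch 1, -0.06 without kdrl:cxcr1 clutch 1 and -0.01 without kdrl:cxcr1 clutch 2. Nuclear oxidative phosphorylation genes stood at -0.06 (adjusted p = 0.65; NDUFA2 2.15 and NDUFV1 1.01). Among other cell types, skeletal muscle stood at -0.27 (adjusted p = 0.421; ckmb -1.97 and MYL1 -1.27), neural genes at -0.20 (adjusted p = 0.863; ELAVL4 1.15 and mbpb 0.90), and mesenchyme and cartilage at 0.17 (adjusted p = 0.795; twist1a 2.41 and TAGLN 1.76). Eye and lens genes stood at 0.21 (adjusted p = 0.863; GNAT2 2.07). Skeletal muscle was called lower without wild-type clutch 2 (-0.89) and without kdrl:cxcr1 clutch 1 (-1.05), and neural genes without wild-type clutch 2 (-0.68). The values of single genes moved as well, with ckmb at -3.01 to -0.93, MYL1 at -2.43 to -0.11 and ELAVL4 at 0.49 to 1.81 when 1 was left out. NDUFA2 ran from 1.49 to 2.81, twist1a from 1.68 to 3.14, TAGLN from 1.2 to 2.31 and GNAT2 from 1.05 to 3.09. No member of these stress, metabolic, muscle, neural and mesenchyme lists passed over all genes or adjusted over the list alone. Among the lists reported here, the median and camera's direction differed in sign for oxidative phosphorylation, matrix remodelling and eye and lens.

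How far the clutches matched was described across genes, which are not independent replicates. The log2 ratio of kdrl:cxcr1 to wild-type in clutch 1 correlated with that in clutch 2 at Pearson's r = 0.106 and Spearman's rho = 0.172, and 56.9% of genes had the same sign. Both kdrl:cxcr1 libraries lay above or both below the wild-type libraries for 7026 genes, 39.6% of those tested. Chance gives 33.3% only if the 4 libraries are exchangeable, which leaves out the pairing by clutch. The same share was 35.9% when the libraries were divided by clutch and 24.4% when kdrl:cxcr1 clutch 1 and wild-type clutch 2 were set against the other 2, both computed after seeing the data. Between single libraries the correlation of log2 values was highest within clutch 1 (Pearson's r = 0.878) and lowest within clutch 2 (0.728). malat1 was higher in kdrl:cxcr1 in both clutches (log2 ratios 3.76 and 2.93), though it did not pass the test.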

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

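The number of genes past limma's threshold was 2 in the analysis as reported, and also with a pseudocount of 5, the stricter filter, both scalings, robust moderation and a threshold of 0.1. It was 0 with a pseudocount of 0.1 (1064 genes at an unadjusted p under 0.05), 0 without a filter (1210), 0 without the trend (1174) and 0 with the clutch as a block (1458). It ranged from 0 to 0 when 1 library was left out (353 to 1589), and was 1, HSP90AB1, among genes above 0 in all 4 libraries, chosen after seeing the data. The adjusted p of HSP90AB1 ran from 0.0067 in that last setting to 0.853 without kdrl:cxcr1 clutch 2. Without a filter 24063 genes were adjusted for, and leaving out a library left 3, with the lone sample assumed to vary like the others. The cause of the other differences was not tested. The block changed no other call. cxcr1 ranged from -1.6 to 2.19 with 1 library left out, and kept its sign under the other settings (0.21 to 0.32). The clutch correlation was 0.061 to 0.141 over its alternatives.

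The count of lists called was 8, between 6 and 9 under the other fits, including each left-out library, and 0 with an estimated correlation and 0 by fry. It was 9 with matching by capitals and 7 without MT-CO1, both chosen after seeing the data. Matching by capitals added skeletal muscle (median -0.79, camera adjusted p = 0.0281) and moved the stem and progenitor median from 0.33 to 0.06. It also turned camera's direction for the interferon, matrix remodelling, Notch, GPCR and neural lists, none of them called. Those turns are not in the counts that follow. Of 448 comparisons of a list with its value under an alternative, camera's direction and call were kept in 376, the call was lost in 29 and gained in 6, and camera's direction turned in 37. No list for which camera's direction turned was called as reported. The values given are list medians, whose sign can differ from camera's direction. Camera's direction turned for adhesion (-0.05) and GPCR (0.01) without a filter, and for interferon (-0.17) and matrix remodelling (-0.06) with the stricter filter. It turned for matrix remodelling (-0.05), Notch (-0.01) and eye and lens (0.25) with median-of-ratios scaling, and for matrix remodelling with quantile normalization (-0.06) and the block (-0.02). With the direction kept, the lipid median crossed to 0.03 with the stricter filter. By fry the direction of the pan-endothelial, venous, GPCR and neural lists differed (adjusted p = 0.986 for each), and adhesion (0.852). fry measures against 0 and camera against other genes, so a sign can differ where all genes shift.

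With 1 library left out, the sign of cxcr1 (in 2 cases, given above), that of 5 further named genes and camera's direction of 15 lists turned in at least 1 case, and the cause was not tested. Log2 fold changes ranged from -1.14 to 2.06 for CXCR1, -0.02 to 0.67 for cxcl18b, -3.25 to 0.36 for b2m, -0.68 to 0.25 for cdh5 and -0.88 to 0.20 for kdrl. The medians of those lists ranged from -0.55 to 0.18 for pan-endothelial, -0.61 to 0.37 for venous, -0.69 to 0.26 for tip cell, -0.08 to 0.33 for Notch and -0.13 to 0.32 for NF-kB genes. They ranged from -0.18 to -0.01 for adhesion, -0.09 to 0.28 for matrix remodelling, -0.52 to 0.07 for stress, -0.28 to 0.12 for GPCR and -0.24 to 0.09 for oxidative phosphorylation genes. For markers of other cells the ranges were 0.02 to 0.44 (stem and progenitor), -1.05 to 0.28 (skeletal muscle), -0.84 to 0.72 (neural), -0.26 to 0.45 (mesenchyme) and -0.63 to 1.03 (eye and lens). Among the lists reported here, medians also crossed 0, with camera's direction kept, for CXCL8 (-0.11 to 1.32), arterial (-0.38 to 0.05), lipid (-0.28 to 0.36) and the called neutrophil and macrophage list (-0.02 to 0.99). Of 1380 comparisons of a named gene other than cxcr1 with its value under an alternative, 1358 kept direction and call, 16 lost the call and 6 turned direction. Only HSP90AB1 and ENSDARG00000080647 had a call to lose, so all 16 losses were theirs. Genes named because their groups do not overlap keep their sign in any case when 1 library is left out. The count kept is therefore no measure of stability. Depth is unknown, so what it limits could not be measured.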

Other observations

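All tests in this part, and the genes named for the clutches, were chosen after the results were seen. Dividing the 4 libraries by clutch in place of genotype gave a difference in cell-type markers. Clutch 2 also listed more of the tested genes at 0, with 1665 in kdrl:cxcr1 and 1477 in wild-type. In clutch 1 these were 272 and 246. How far such zeros make the differences between clutches was not tested. Transcripts of skeletal muscle were higher in clutch 1, with a list median 1.28 log2 units above that of all genes (camera adjusted p = 1.24e-05), as were neural transcripts (1.16, adjusted p = 1.24e-05) and the epidermal list (0.94, adjusted p = 0.0234). These calls were lost with an estimated correlation (adjusted p = 0.485, 0.485 and 0.88 with an estimated correlation). MYL1 (ENSDARG00000014196) read 41.3 and 62.5 FPKM in kdrl:cxcr1 and wild-type of clutch 1 and 7.44 and 31.6 FPKM in clutch 2, the neuronal gene ELAVL3 92.4 and 115 against 50.4 and 19.9, and the myelin gene mbpa 10 and 14.1 against 0.0808 and 0.119. Of 4 lists of endothelial markers, 3 were higher in clutch 2, with the pan-endothelial median at -0.62 for clutch 1 minus clutch 2 (adjusted p = 7.65e-05) and the tip cell (-0.67, adjusted p = 0.000515) and venous (-0.55, adjusted p = 0.0109) lists alongside, while the arterial list stood at -0.06 (adjusted p = 0.637). Those 3 calls too were lost (adjusted p = 0.485, 0.485 and 0.706 with an estimated correlation). The stress list (-0.35, adjusted p = 0.00537) and the neutrophil and macrophage list (-0.63, adjusted p = 0.0145) were also higher in clutch 2 (adjusted p = 0.485 and 0.88 with an estimated correlation). The endothelial transcription factor gene ERG read 17.1 and 13.5 FPKM in clutch 1 and 28.8 and 41.5 FPKM in clutch 2, and rasip1 17.9 and 17.5 against 32.9 and 50.8. The calls made 8 lists by clutch, as many as the 8 by genotype, and 0 were kept with an estimated correlation in either of these or in the crossed division described next. limma called 3 genes by clutch and 5 in the crossed division, which sets kdrl:cxcr1 clutch 1 and wild-type clutch 2 against the other 2 libraries, compared with 2 by genotype.

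Several genes lay near 0 in both libraries of 1 genotype and high in both of the other, HSP90AB1 and MT-CO1 among them. With bounds of at least 100 FPKM and under 10 FPKM there were 4 such genes by genotype, 5 by clutch and 4 in the crossed division. HSP90AB1 was among those by genotype, but not MT-CO1, at 88.6 FPKM in kdrl:cxcr1 clutch 2. SNORD46 was in the crossed division (735 and 4920 FPKM against 0 and 0). Values that switch from library to library without regard to genotype could therefore account for these genes. At these bounds the only genes with a symbol in the clutch and crossed divisions were SNORA77B and SNORD46, both small nucleolar RNAs. The counts therefore do not show that the values of protein-coding genes such as HSP90AB1 and MT-CO1 switch in this way. Of 6 pairs of bounds examined, the crossed division gave at least as many genes as genotype in each, for example 21 against 15 at 10 and 1 FPKM. A loss of mitochondrially encoded RNA as a whole was argued against for MT-CO1, since the other 12 such mRNAs had a median log2 fold change of -0.44 (SD 0.62), and reads of HSP90AB1 counted on its paralog HSP90AA1 were argued against because HSP90AA1 was 129 FPKM higher (SE 153) in kdrl:cxcr1, where HSP90AB1 gained 651. A difference in these genes made by the genotype stays open and untested.

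The proliferation list was higher in kdrl:cxcr1 by 0.54 log2 units, and 3 accounts were weighed beside an effect of the genotype, which stays open and was not tested. A larger endothelial share stays open: the pan-endothelial median was -0.21, below the proliferation median by more than the 0.56 SD of its members, but the gap was 0.31 without wild-type clutch 2 (SD 0.41) and 0.52 without kdrl:cxcr1 clutch 1 (SD 0.69). More RNA of dividing blood cells could add to the list and cannot be told apart from a genotype effect, because the stem and progenitor list (0.33) and the erythroid list (0.61) lay above the median gene. Of the 3 divisions of the 4 libraries, 1, the genotype itself, gave a p as small (2.51e-05, against 0.111 in the crossed and 0.52 in the clutch division), and 3 divisions are too few for a share under 0.05.

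The epidermal list was lower in kdrl:cxcr1, but the crossed division also called it (median 0.74, adjusted p = 0.000865; adjusted p = 0.839 with an estimated correlation, where the genotype call was lost too), and its genotype median was -0.24 in clutch 1 and -1.63 in clutch 2. Carry-over of skin cells that differs from library to library is a candidate explanation, and krt4, at 240 and 343 FPKM in clutch 1 and 45.6 and 379 FPKM in clutch 2, was lowest in kdrl:cxcr1 clutch 2. Sorting on kdrl:mcherry should remove such cells, and how many of the 26 genes endothelium also expresses was not examined. An effect of the genotype on these transcripts stays open and was not tested.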
